A study of Mus musculus with 2 samples.

How the data were processed

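H3K4me2 ChIP-seq was performed on intestine of newborn mice in 2 biological replicates of 1 group, each a pool of animals, with a library size range of 300 to 500 bp per the labels. The authors deposited 4 peak lists on the mm10 assembly, 1 per replicate, 1 pooled and 1 of replicated peaks. Per the accompanying text files, the peaks of each replicate were called on its own alignments against a control alignment that differed between the replicates, the pooled list used the alignments and controls of both, and the replicated list was derived from the other lists. The caller, its version and the rule behind the replicated list are not given in the sources used here. Each peak in the deposited lists has a signal value, an enrichment whose scale the authors do not state, and a -log10 p of the caller. The deposited -log10 p was at least 2.01 in both replicate lists and the pooled list, so that weak peaks were kept. The deposited summit offset was used to place windows. Signal values and -log10 p are the authors' own values per peak, and were used here to describe, rank and filter peaks. Since the scaling between libraries is not stated, signal values of the replicates were compared by rank and on a log scale only, and their means are descriptive. The lists hold no read counts, so depth per library is unknown and its part in the number and width of peaks could not be measured.

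Coordinates were checked against the GRCm38 reference, the assembly also called mm10. No peak on chromosomes 1 to 19, X and Y ended past its chromosome. Between 13 and 16 peaks per list on unplaced scaffolds were left out of every comparison with the annotation. Genes came from GENCODE M21, with 21829 protein-coding genes and 54322 start sites of their protein-coding transcripts. A gene was marked when a peak reached within 1 kb of any of its start sites. Peaks up to 1 kb apart were joined into domains, and a gene's domain was the widest that reached that window. A distal peak had its centre more than 2.5 kb from every start site and was given to the nearest gene within 100 kb. A wide peak that reached a promoter window, or a piece of a domain joined to such a peak, could therefore also count as distal. Peaks were assigned in order to promoter, exon, intron and intergenic sequence. A peak counted as shared when at least 50% of its length was covered by the other list. Shuffled placements (100, fixed seeds) kept each peak's chromosome and width and left out assembly gaps. Shares of a single list have Wilson 95% intervals, which cover counting error only.

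The 25 gene lists, the rule for the genes named in the text and the alternatives below were fixed before the data were examined. Of 341 list entries, 340 were matched to the annotation, including the gene Gif under its older symbol, and Ahsp was not matched. Lct stood in 2 lists. Promoter share and median domain width (0 bp where a gene had no promoter peak) were ranked among 10000 random lists of the same size. These had the same deciles of CpG observed/expected ratio within 500 bp of the gene record's 5' end. A gene could be marked at any of its start sites, so the matched sequence need not be the promoter that was marked. The mean number of distal peaks was ranked among lists with the same deciles of territory. Territory is the distance between the neighbouring genes' start sites, limited to 100 kb on each side. Percentiles count ties by their middle rank. The 95th and 5th percentiles were used as marks. They are descriptions of these lists, and 25 lists were ranked for each of 3 measures. Some list genes are known in more than 1 of the tissues listed, and defensin genes have near-identical copies in which peaks can be missed. The named genes were the genes of the 10 widest domains, the nearest genes of the 10 strongest peaks, the widest-domain pair, the first pair without a promoter peak in alphabetical order and the gene with the most distal peaks of each list, and the 5 strongest promoters marked in each replicate only. Ties for most distal peaks were broken by genome order. Cdhr5 was named outside this rule, after the values were seen.

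For motifs, windows of 300 bp at distal summits were searched on both strands for 17 consensus words fixed beforehand, and the share of windows with a word was divided by the share in 10 copies of each window shuffled with their dinucleotides kept. A first count used 1 copy, and 10 were chosen after its values were seen, because rare words were imprecise. The ratio of 1.2 used to count words was set after the deposited lists had been opened. Alternatives covered a stricter threshold (-log10 p of at least 5), other overlaps, windows, joining and reach distances, the pooled list, each replicate alone, unmatched random lists and flanking windows as motif background. Flanking windows of the same GC content, in bins of 2 points, were a comparison chosen after the ratios over all flanking windows were seen. An alternative added after seeing the data used the pooled peaks at least 50% covered in both replicates.

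The statistics were tested on simulated data. For the overlap of the replicates, with 60.0% of 57541 peaks copied, 60.6% were recovered. For the promoter share, 3.50% of 200 simulated lists with no effect and 100% of 200 lists with 95% of 15 genes marked reached the 95th percentile. Shuffling kept the dinucleotide counts of all 200 windows examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, bedtools 2.31.1 and samtools 1.23.1 were used.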

Results

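Dimethylation of histone H3 at lysine 4 (H3K4me2), a chromatin mark found at promoters and enhancers, was mapped by ChIP-seq in whole intestine of newborn mice of both sexes (postnatal day 0). The series held 1 group of 2 biological replicates. Replicate 1 was a pool of intestine from 15 mice, and the number of mice in the pool of replicate 2 is not given in the sources used here. Replicate 1 gave 57554 peaks over 56.1 Mb and replicate 2 gave 68124 peaks over 51.1 Mb (62839 ± 7474 peaks, SD, n = 2). The deposited list of replicated peaks, on which the values below rest unless another list is named, held 42394 peaks over 56.5 Mb. Read depth is unknown, because the lists carry no read counts. With 1 group, no difference between conditions could be tested, and no p-value is given across genes or peaks, which are not replicates. The comparisons asked which cell types' genes carried the mark, where in the genome it lay, and how far the replicates shared it. Each gene list is set beside 10000 random lists matched on promoter CpG content or, for distal peaks, on the gene's territory. The median domain of a list is taken over all its genes, and a gene without a promoter peak counts as 0 bp. An absent peak means only that none was called in a mixture of cells, where genes of rare cells can stay below the calling threshold. A peak counted as distal can be a piece of a broad domain that also reaches the gene's promoter.

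Regulators and effector genes of the intestinal epithelium carried broad H3K4me2 domains. Of 20 epithelial transcription factor genes, 19 had a promoter peak (97.5% ± 3.54 over the replicate lists, SD, n = 2), and their median domain of 7055.5 bp compared with 1822 bp in random lists, above all of them. Cdx2, the homeobox gene that sets intestinal identity, lay in a domain of 19256 bp (19194 ± 230 bp, n = 2) on chromosome 5 from 147298903 to 147318158, which covered the whole gene and its upstream flank. The domain of Gata4, a GATA factor of the proximal intestine, measured 17823 bp (19131 ± 3457 bp, n = 2) on chromosome 14 from 63235209 to 63253031. Prdm1, a repressor that holds back the adult enterocyte programme before weaning, had 15 distal peaks and Gata4 had 14. In the longer replicate lists Prdm1 had 23.5 ± 0.707 and Gata4 24.5 ± 3.54 (n = 2). Creb3l3, a lipid-responsive transcription factor gene of liver and intestine, lacked a replicated promoter peak, although replicate 2 had one with a domain of 345 bp. The mean number of distal peaks near these factor genes was 5.55, against 1.3 in random lists, and 8.75 ± 0.990 in the longer replicate lists (n = 2). Part of these counts can come from pieces of the genes' own broad domains, and that part was not measured.

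**Figure D1:**
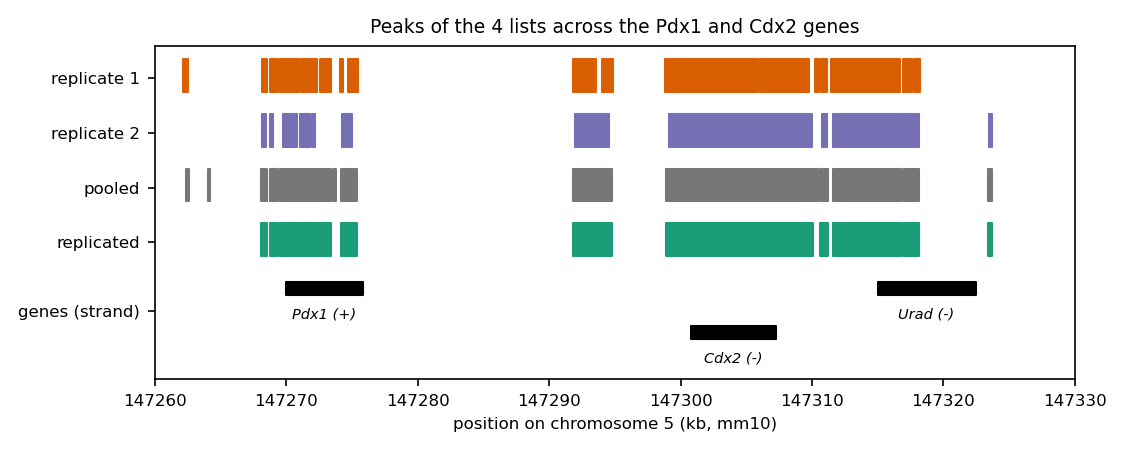
Peaks of the 4 deposited lists (coloured bars, to scale) along chromosome 5 (horizontal axis, kb, mm10) across Pdx1 and Cdx2, with protein-coding genes as black bars and their strand in brackets. In the replicated list a domain of 19256 bp covers Cdx2 and a domain of 7267 bp covers the start of Pdx1.

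Of 22 enterocyte genes, 21 had a promoter peak in both replicates, a share of 95.5%, where random lists had a median of 36.4%. Their median domain was 4582.5 bp (4829.5 ± 175 bp, n = 2), against 0 bp in random lists, where most genes had no promoter peak and counted as 0 bp. Among all genes with a promoter peak, the median domain was 2501.5 bp and the 95th percentile 6131 bp. Anpep, which encodes the brush border aminopeptidase N, had a domain of 11709 bp (11068 ± 890 bp, n = 2), and Lgals4, which encodes a lectin of the apical membrane, one of 9148 bp (9080 ± 187 bp, n = 2). Cdh17, the liver-intestine cadherin gene, had 6 distal peaks (10 ± 1.41 in the replicate lists, n = 2). Sis, which encodes the sucrase-isomaltase that appears at weaning, was the 1 gene of the list with no promoter peak, and none was called in any of the 4 lists. All 8 genes of neonatal protein uptake were marked, with a median domain of 4575.5 bp against 1570 bp in random lists. Among them Fcgrt, whose product carries maternal IgG across the epithelium, had 7168 bp (7415 ± 600 bp, n = 2), and Ass1, an enzyme gene of arginine synthesis, had 5624 bp (4812 ± 907 bp, n = 2) and 6 distal peaks (10.5 ± 2.12, n = 2).

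Stem cell genes on the list were all marked, Paneth cell genes lacked a replicated promoter peak, and enteroendocrine genes had a low median domain width. All 15 stem cell and Wnt target genes had a promoter peak, where random lists had a median share of 86.7% (percentile 97.1, but 83.3 from the gene record's 5' end). Their mean of 4.87 distal peaks (7.5 ± 1.18 in the longer replicate lists, n = 2) compared with 1.47 in random lists for the replicated list. Lrig1, an inhibitor of growth factor receptors in stem cells, had a domain of 9944 bp (10322 ± 677 bp, n = 2) and 17 distal peaks (29 ± 5.66 in the replicate lists, n = 2), and Sox9, a factor of crypt progenitors, had a domain of 8340 bp (8697 ± 469 bp, n = 2). Among 12 goblet cell genes, 8 had a promoter peak. The median domain over all 12, with unmarked genes counted as 0 bp, was 447.5 bp against 135.5 bp in random lists (percentile 62.7). The widest domains were at Gfi1 (6272 bp, 5002 ± 1621 bp, n = 2) and Creb3l1 (4162 bp), both transcription factor genes, and there was none at Clca1 and Retnlb, which encode secreted goblet cell products. The goblet share sat exactly at the 95th percentile and kept that side in 1 of 9 alternatives (percentiles 42.5 to 98.2). None of 11 Paneth cell genes had a replicated promoter peak, Ang4, Defa17, Itln1 and Reg3b (all genes of secreted antimicrobial or lectin proteins) among them, and none had a distal peak. Their promoter share lay at percentile 4.22, and at 16.5 in replicate 2, where 1 gene was marked. It stayed at or below the 5th percentile in 6 of 9 alternatives. Enteroendocrine genes were marked in 12 of 18 cases. Over all 18, with unmarked genes counted as 0 bp, the median domain was 493 bp (435 ± 47.0 bp, n = 2) against 1767 bp in random lists (percentile 0.310, but 5.11 among random lists not matched on CpG content). The widest were Sct (6843 bp), the secretin gene, whose domain is shared with the neighbouring enterocyte gene Cdhr5, and Pax6 (4384 bp, 3610 ± 964 bp, n = 2), a factor of hormone-producing cells. Arx, a factor of the same lineage, and Gcg, the proglucagon gene, lacked a replicated promoter peak, although Arx had one of 627 bp in replicate 2. Of 8 tuft cell genes, 3 were marked, Dclk1 (1515 bp), a kinase gene, and Chat (1323 bp, 1180 ± 507 bp, n = 2), the acetylcholine synthesis gene, most widely, whereas Avil and Gfi1b were not.

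Smooth muscle and mesenchyme genes were also broadly marked, and genes of enteric nerves and of the interstitial cells of Cajal lay within the random range in width. All 11 smooth muscle genes had a promoter peak, with a median domain of 4598 bp (4128 ± 113 bp, n = 2) against 1493 bp in random lists. Without joining of neighbouring peaks, this width fell to percentile 79.3. The widest belonged to Myh11, the smooth muscle myosin gene (5693 bp, 4031 ± 2099 bp, n = 2), and Myocd, its coactivator (5413 bp, 5221 ± 250 bp, n = 2), while Mylk, the myosin kinase gene, had 10 of the list's 26 distal peaks (19 ± 7.07 in the longer replicate lists, n = 2). All 16 mesenchyme genes were marked, at a median of 6381.5 bp (5483 ± 88.0 bp, n = 2, but 2949.5 bp without joining and 3836 bp in pooled peaks covered in both replicates, an alternative added after seeing the data) against 1634 bp. Foxf1, a Hedgehog target of the gut mesenchyme, had a domain of 18412 bp (19514 ± 2783 bp, n = 2) on chromosome 8 from 121072582 to 121090993, Nkx2-3, a homeobox factor of the same tissue, one of 13300 bp (13092 ± 146 bp, n = 2), and Col1a1, a collagen gene, had 8 distal peaks. In the enteric nervous system list 13 of 15 genes had a promoter peak (percentile 87.9), and the median domain over all 15 was 1700 bp against 1941 bp in random lists (percentile 21.25). Hand2 (9991 bp), a factor of enteric neurons that gut mesenchyme also uses, and Erbb3 (7223 bp), a receptor of glial precursors, were the widest, and Phox2b and Plp1, genes of enteric neurons and glia, had none. The 3 genes of the interstitial cells of Cajal, the pacemaker cells, were all marked, Etv1 over 4138 bp and Kit over 3027 bp, with the median width at percentile 88.2.

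Most endothelial genes had a promoter peak, the share of erythroid genes lay within the random range, and that of immune genes depended on the choices made. Of 15 endothelial genes, 13 had a promoter peak, Prox1 (7070 bp, 5143 ± 2679 bp, n = 2), a lymphatic factor, and Esam (6110 bp, 4405 ± 599 bp, n = 2), an adhesion molecule gene, most widely, and Cdh5, the VE-cadherin gene, had 8 distal peaks (11.5 ± 2.12, n = 2). This share differed between the replicates (83.3% ± 14.1, n = 2): it was 93.3% in replicate 1 but 73.3% in replicate 2, at percentile 54.1, and it kept its place above the 95th percentile in 4 of 9 alternatives. Pecam1 and Lyve1, a pan-endothelial and a lymphatic gene, lacked a replicated promoter peak. Of 14 immune cell genes, 3 were marked (percentile 10.7, at or below the 5th percentile in 4 of 9 alternatives and at 61.6 in the pooled list), Coro1a (1873 bp) and Ikzf1 (1807 bp), an actin regulator and a lymphoid factor, most widely, and Cd19 and Adgre1, B cell and macrophage genes, were not. Spi1, a myeloid factor, had no replicated promoter peak but 2 distal peaks. Cd19 and Spi1 had a promoter peak in the pooled list. Of 10 erythroid genes, 5 were marked (percentile 78.7), among them Tal1 (4281 bp) and Klf1 (1984 bp), both transcription factor genes, and Alas2 and Epb42, genes of haem synthesis and the red cell membrane, were not.

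Stomach and oesophagus, photoreceptor and germ cell genes were marked less often than random lists, striated muscle genes less often in 5 of 9 alternatives, and pancreas and liver genes lay within the matched random range, though at percentiles 1.505 and 0.680 of unmatched lists. In the pancreas list 5 of 13 genes had a promoter peak (percentile 14.6), with Pdx1 (7267 bp, 5694 ± 2273 bp, n = 2), which duodenum and pancreas share, and Nkx6-1 (2563 bp), a beta cell factor, the widest, and the digestive enzyme genes Cel and Cpa1 unmarked. In the liver list 5 of 14 did (percentile 27.8), led by Cps1 (13032 bp, 12906 ± 3.54 bp, n = 2, with 7 distal peaks, 10.5 ± 0.707 in the replicate lists), a urea cycle enzyme gene that intestine also uses, and Apoh (3771 bp), a plasma protein gene, while Afp and Ahsg, both for fetal plasma proteins, lacked a replicated promoter peak. Of 12 stomach and oesophagus genes, 2 were marked (percentile 0.725), Sox2 (2905 bp), a foregut factor, and Barx1 (982 bp, with 9 distal peaks), a factor of stomach mesenchyme, and the proton pump genes Atp4a and Atp4b had no replicated promoter peak. Striated muscle genes were marked in 4 of 14 cases (percentile 1.76), Acta1 (2516 bp, but 483 bp in replicate 1) and Ryr1 (1945 bp, 1848 ± 122 bp, n = 2), for actin and a calcium channel, most widely, with no replicated promoter peak at Ckm and Myf5, but the share lay at percentile 6.12 in replicate 1, 15.0 in replicate 2, 14.2 in the pooled list and 13.9 within 2.5 kb. Photoreceptor genes were marked in 1 of 10 cases (percentile 0.300), Opn1sw (921 bp), an opsin gene. Cnga1 and Crx were unmarked, and Gnat1 had 1 distal peak. Germ cell genes were marked in 2 of 10 cases, Dazl (1014 bp), an RNA-binding protein gene, and Sycp3 (542 bp, 787.5 ± 238 bp, n = 2), a meiosis gene, with Ddx4 and Figla unmarked and 3 distal peaks near Tnp1, although replicate 2 marked 5 of these genes and replicate 1 marked 2. By contrast 13 of 14 forebrain genes had a promoter peak (percentile 97.2), Bcl11b (9031 bp, 15 distal peaks), a factor also of lymphocytes, and Satb2 (5418 bp), a chromatin organiser, most widely, and Neurod6 none. Their mean of 3.43 distal peaks compared with 1.36 in random lists (percentile 99.8) and stayed above the 95th percentile in 8 of 8 alternatives. None of these left out Bcl11b, which had 15 of the forebrain list's 48 distal peaks. Without it the mean fell to 2.54, within the middle 95% of random lists for the whole list (0.5 to 2.71). In replicate 2 the forebrain promoter share fell to percentile 84.1, and it stayed above the 95th percentile in 5 of 9 alternatives. All 16 housekeeping genes were marked, where random lists had a median share of 87.5%. Their median domain of 4287 bp (3792 ± 130 bp, n = 2) against 2423 bp in random lists (percentile 99.99) was about as wide as those of the enterocyte and smooth muscle lists. Rpl13a (8651 bp, 6090 ± 3270 bp, n = 2), a ribosomal protein gene, and Actb (7741 bp), the beta-actin gene, were the widest. Ywhaz had 13 of that list's 27 distal peaks, and the mean fell from 1.69 to 0.933 without it.

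**Figure D2:**
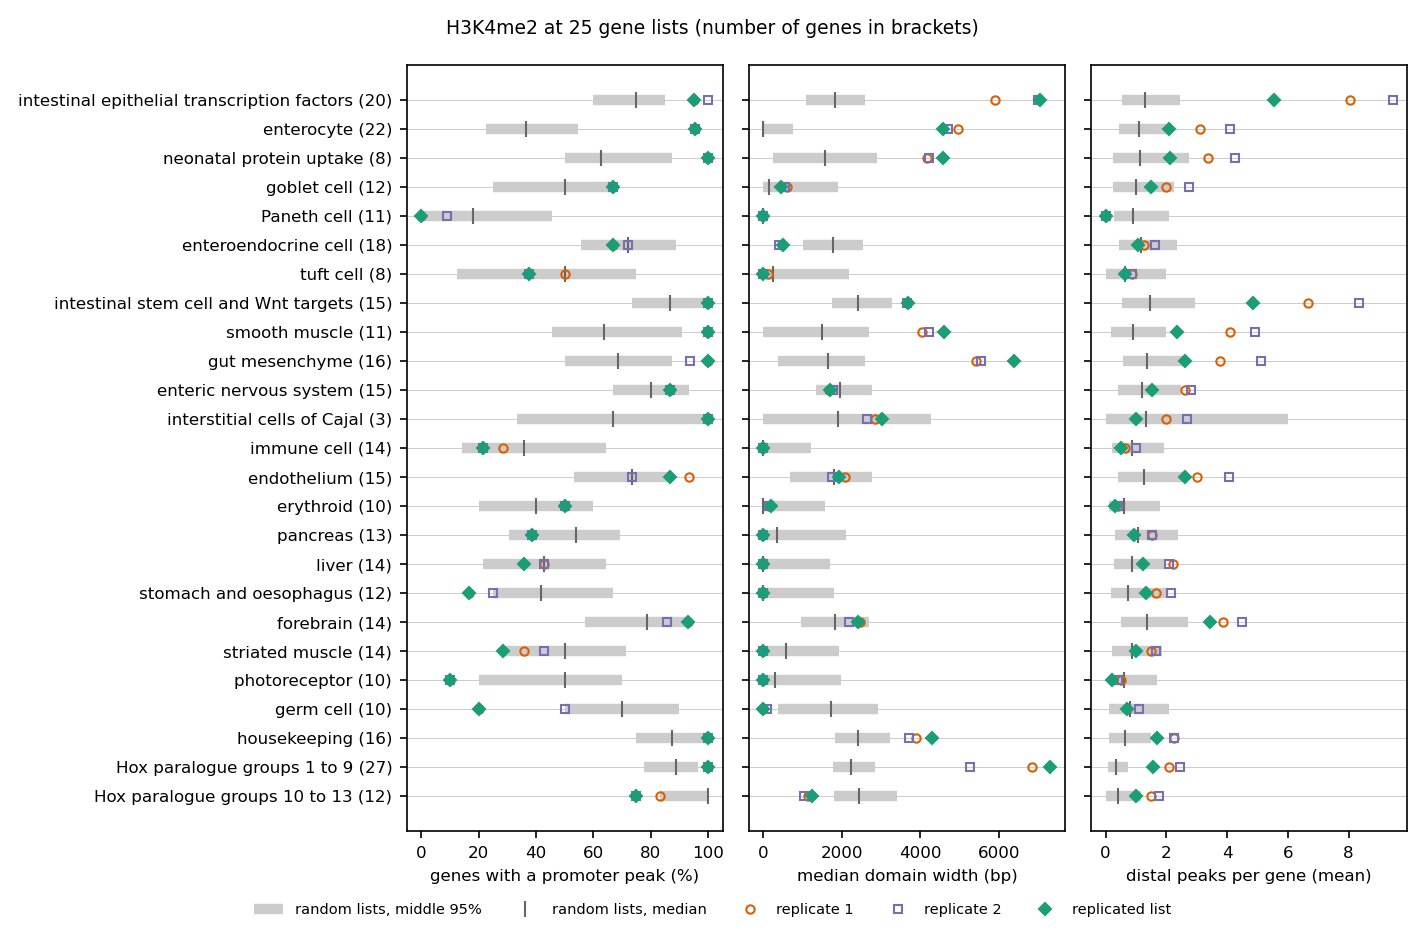
For each of 25 gene lists (rows, number of genes in brackets), the share of genes with a promoter peak (%), the median domain width (bp) and the mean number of distal peaks per gene, for the replicated list (filled diamonds), replicate 1 (circles) and replicate 2 (squares), beside the median (tick) and the middle 95% (grey bar) of 10000 matched random lists. Epithelial factor, enterocyte, neonatal protein uptake, stem cell, smooth muscle, mesenchyme, housekeeping and anterior Hox genes lie right of the grey bars in width. Enteroendocrine genes, germ cell genes and the 10 to 13 paralogue groups lie left of theirs in width.

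In the Hox clusters, which pattern the body from head to tail, median domain width differed between paralogue groups, with overlap of single genes. All 27 genes of groups 1 to 9 had a promoter peak, where random lists had a median share of 88.9%. Their median domain was 7315 bp (6057 ± 1123 bp, n = 2) against 2231 bp in random lists. That median was 3253 bp without joining and 25477 bp with joining up to 3 kb, above the 95th percentile in each case. Of the 12 genes of groups 10 to 13, 9 had one. The median domain over all 12, with unmarked genes counted as 0 bp, was 1236.5 bp (1084 ± 61.2 bp, n = 2) against 2440 bp in random lists, at percentile 0.01. Hoxb3 to Hoxb6 shared the widest domain of the genome, 38247 bp (37715 ± 426 bp, n = 2) on chromosome 11 from 96291636 to 96329882, and Hoxb9 had 7 distal peaks. The widest of the posterior group were Hoxa10 (6856 bp, 11004 ± 6190 bp, n = 2) and Hoxa11 (6188 bp, 6160 ± 31.1 bp, n = 2), while Hoxc11 and Hoxc12 had no replicated promoter peak. In replicate 1 the domain of Hoxa10 measured 15381 bp, as did those of the Hoxa genes of groups 7 and 9. Groups 1 to 9 in turn held a domain as narrow as 929 bp, in the Hoxb cluster. The width of the posterior group lay above the 5th percentile when peaks up to 3 kb apart were joined (percentile 11.2) and among random lists not matched on CpG content (22.1).

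The 10 widest domains lay at Hox genes, at other regulatory genes and at runs of neighbouring genes. After the Hoxb domain came one of 24147 bp over Hoxa1, Hoxa2 and the adjacent 5730596B20Rik (chromosome 6, 52157257 to 52181403), one of 22391 bp at Ptch1, the Hedgehog receptor gene (chromosome 13, 63551699 to 63574089), and one of 21409 bp at Meis2, a homeobox cofactor of Hox proteins (chromosome 2, 116055246 to 116076654). Cdx2, Foxf1 and Gata4 were the 6th, 7th and 10th, and Onecut2, a homeobox factor of endoderm, held 18217 bp (chromosome 18, 64331965 to 64350181). A pair of domains spanned runs of genes instead, Dbp, Rpl18, Sphk2 and Fam83e on chromosome 7 (19941 bp, 45703555 to 45723495) and Mamdc4, Phpt1 and Ajm1 on chromosome 2 (17897 bp, 25564513 to 25582409). The width of these domains varied little between replicates at Hoxb3 to Hoxb6 and Cdx2, more at Ptch1 (22097 ± 3585 bp, n = 2). The rank rests on the joining distance, since 5 of the 10 were still among the widest with no joining and 4 with joining up to 3 kb.

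The peaks with the highest signal values lay at another set of genes. These are single peaks that were not joined, so their widths cannot be compared with those of the widest domains. The 10 strongest measured 1662 to 3823 bp, and 9 had their summit at a promoter, in a coding exon at Mmp17, Cspg5, Cited4, Nanos1 and Gls2 and in an untranslated exon at March9, Ntn4, Mpped2 and Wiz. Mmp17, a membrane metalloproteinase gene, ranked first with a signal value of 70.04 (56.9 ± 16.0, n = 2), on chromosome 5 from 129583243 to 129586647. The exception lay outside genes on chromosome 6 from 51269030 to 51271882, with a signal value of 64.9, and its nearest protein-coding gene was Nfe2l3, 161904 bp away. The order among these peaks is within the spread between the replicates.

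H3K4me2 was concentrated at promoters. Of the replicated peaks, 39.4% lay within 1 kb of a protein-coding transcription start site, against 4.21% of shuffled placements, a 9.36-fold excess (31.0% ± 0.803 in the replicate lists, n = 2). Promoter peaks were wide (median 2007 bp) and strong (median signal value 26.6) and held 65.3% of all covered bases. Introns held 26.9% of peaks and intergenic sequence 27.0%, where shuffled placements put 30.9% and 56.7%. In replicate 1, replicate 2 and the pooled list the intron share turned, at 34.2%, 35.1% and 35.2% against 32.3%, 33.2% and 32.3% in shuffled placements of their own peaks. Altogether 15036 of 21829 protein-coding genes (68.9%) had a promoter peak, and the median domain of these marked genes alone was 2501.5 bp. The share rose with promoter CpG content, from 8.34% of genes in the lowest decile to 99.4% in the highest. By their centre, 23707 peaks were distal, more than 2.5 kb from every start site, at a median distance of 19.9 kb. A wide peak can be counted both here and at a promoter. The share at promoters depended on the list and was 28.8% in the pooled list.

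The replicates marked nearly the same genes at their promoters, shared nearly all strong peaks, and differed mainly in weak ones. Of all protein-coding genes, 14958 had a promoter peak in both replicates, 169 in replicate 1 only and 302 in replicate 2 only. The strongest of the first kind were at Lck (27.2), a T cell kinase gene, Hist1h1d (24.3), a linker histone gene, Art1 (21.4), Tslp (13.8), an epithelial cytokine gene, and Rs1 (10.1), and of the others at Tsks (47.8), Vpreb1 (9.42), Prss27 (9.42), Sh2d4b (8.49) and Gm11444 (7.72), each with its signal value. Of the 169 and 302 genes, 47 and 42 had a promoter peak in the replicated list, among them all those named except Lck and Sh2d4b. Peaks this strong were mostly covered by the other replicate, as given below. The peak itself thus need not be absent there, and a peak just outside the 1 kb window was not looked for. Genes marked in replicate 1 only or replicate 2 only had a low median signal value (3.57 and 3.49) and CpG-poor promoters (median observed/expected ratio 0.245 and 0.240, against 0.697 for genes marked in both). Of the peaks of replicate 1, 60.7% (Wilson 95% interval 60.3 to 61.1) were covered over at least 50% of their length by replicate 2, and 63.5% (63.1 to 63.8) the other way round, where shuffled placements gave at most 2.08% and 2.37%. Coverage was 22.9% and 23.6% in the lowest decile of signal value and at least 99.4% in the highest 3 deciles of each list. The intervals cover counting error only. Across 38254 pooled intervals that both replicates covered, signal values correlated with a Spearman rho of 0.890 and a Pearson r of 0.919 on the log2 scale. These are correlations across intervals, which are not independent replicates.

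**Figure D3:**
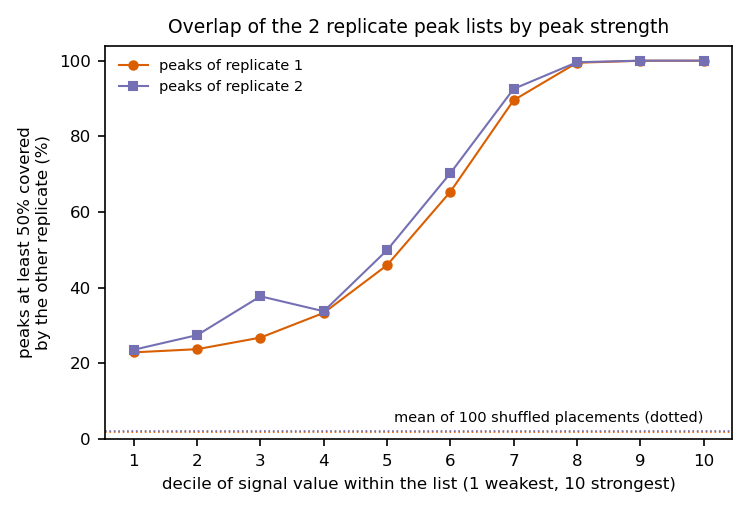
Share of peaks covered over at least 50% of their length by the other replicate (vertical axis, %) by decile of signal value within each list (horizontal axis), for replicate 1 (circles) and replicate 2 (squares), with the mean of 100 shuffled placements as dotted lines. Coverage is 22.9% and 23.6% in the weakest decile and at least 99.4% in the 3 strongest.

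Peaks found in 1 replicate alone were short and rarely at promoters. Those of replicate 1 that shared no base with replicate 2 numbered 16691 (29.0%), with a median width of 264 bp against 846 bp for shared peaks, a median signal value of 3.25 against 7.19, and 6.84% at promoters against 41.7%. Those of replicate 2 numbered 20940 (30.7%), with 202 bp against 611 bp, 3.14 against 6.70 and 7.40% against 40.7%. Of the pooled peaks, 52.1% were covered over at least 50% of their length in both replicates, and of the replicated peaks 77.7%. Every replicated peak was identical to a pooled peak. Of the 32929 pooled peaks covered in both replicates, 32928 were in the replicated list, which held another 9453 peaks that were not.

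Words of several factor families were more frequent at distal summits than in shuffled windows. Against flanking windows the CDX ratio turned below 1, and those of GATA, TEAD and MEF2 stayed above 1 but fell below 1.2. Each of these words was above 1.2 against flanking windows of the same GC content. In 300 bp windows at 23704 distal summits, the word of the FOXA factors, pioneer factors of the gut, was present in 3.93% against 1.59% of shuffled windows (ratio 2.48, 2.18 ± 0.116 in the replicate lists, n = 2, but 1.33 against flanking windows). The GATA word was present in 7.75% against 5.11% (ratio 1.52, 1.48 ± 0.0170, n = 2, but 1.18 against flanking windows and 1.56 against those of the same GC content), and the word of HNF4, the nuclear receptors of enterocytes, in 1.31% against 0.903% (ratio 1.45, 1.55 ± 0.164, n = 2). The CDX word was the most frequent, at 15.7% against 9.43% (ratio 1.67, 1.58 ± 0.0152, n = 2), but against flanking windows, which held it at 21.9%, its ratio was 0.717, and 1.26 against those of the same GC content. Ratios were also above 1.2 for KLF (3.47), ETS (1.65), TEAD (1.67), MEF2 (2.60) and CTCF (4.66), the insulator protein, but against flanking windows TEAD (1.13) and MEF2 (1.12) were below it and against those of the same GC content above it (1.29 and 1.89). ETS had 3.15 against flanking windows, and KLF 1.63 against those of the same GC content. The control word of the neuronal NEUROD factors had a ratio of 1.34 (1.35 ± 0.000783, n = 2), 1.203 against flanking windows and 0.923 against flanking windows of the same GC content. Those of HNF1, ELF/EHF and NRF1 rested on 30, 13 and 26 windows, and a ratio for so few was imprecise. AP-1 (1.04), SOX (1.10) and TCF (1.02) words were close to their background, and the word of SRF, a smooth muscle regulator, was less frequent than in shuffled windows (0.734, 0.711 ± 0.0189, n = 2), but not than in flanking windows of the same GC content (1.02). In all, 13 of 17 words, the control among them, reached a ratio of 1.2, and 9 did against flanking windows.

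**Figure D4:**
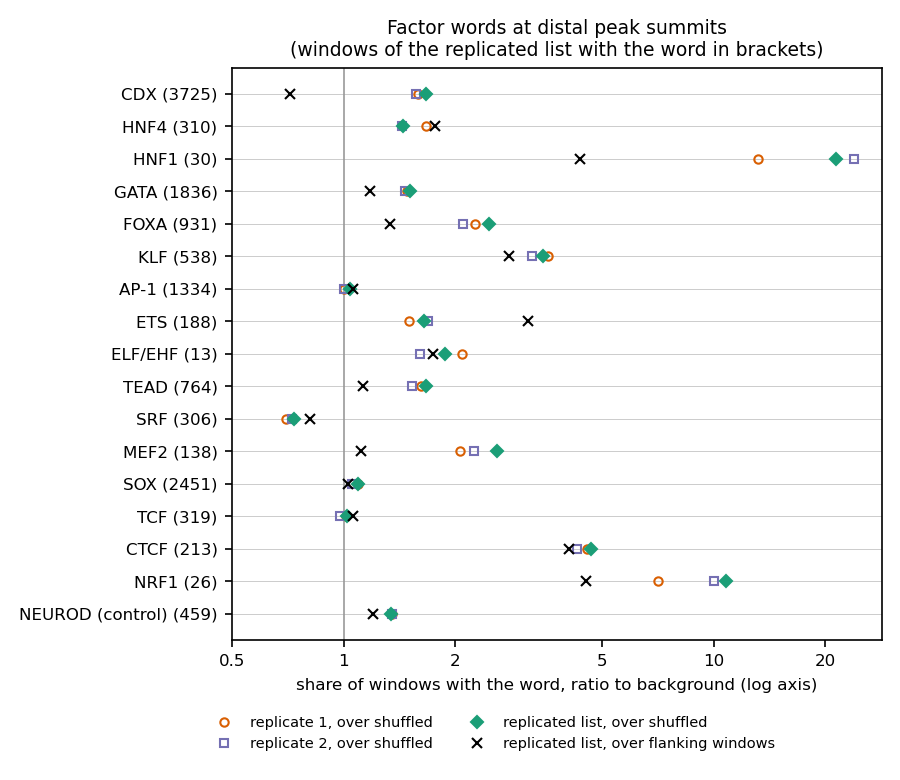
Share of distal summit windows with each factor word over its background (horizontal log axis), for the replicated list (diamonds), replicate 1 (circles) and replicate 2 (squares) over shuffled windows, and for the replicated list over flanking windows (crosses), with the number of windows that hold the word in brackets. CDX lies at 1.67 over shuffled windows and at 0.717 over flanking windows.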

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

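No test was chosen for this result after it was seen. The unplaced scaffolds, which no comparison uses, held 13 peaks of the replicated list on 6 scaffolds, with a median signal value of 8.43 and a highest of 12.9. They were singled out because they are a signal outside the main measurement, and control peaks to set them against were not used here. No biological explanation was tested.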

How the results depend on the processing

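The alternatives were chosen before the data were examined, except pooled peaks at least 50% covered in both replicates and 1 shuffled copy per motif window, which were added after seeing the data. The cause was not tested unless named. Under a -log10 p of at least 5, replicate 2 had 42333 peaks. Coverage of replicate 1 by replicate 2 was 71.0% with 1 shared base, 45.6% with 75% covered, 53.0% with reciprocal overlap, 72.0% under the stricter p and 58.4% with equal numbers of peaks. The other way round it was 69.3%, 55.9%, 44.8%, 79.5% and 70.8%. Looser and stricter overlaps move these values by construction. The rho was 0.909 on the p column, 0.892 over replicated intervals and 0.886 with length-weighted means. Support of pooled peaks in both replicates was 60.6% with 1 base, 35.1% with 75% covered and 42.5% under the stricter p, and 66.2% to 75.2% with a replicate left out. Replicate-specific peaks were 39.3% and 36.5% when counted as under 50% covered, and 21.7% and 17.3% under the stricter p. The promoter share was 37.7% within 500 bp, 45.8% within 2.5 kb, 28.8% in the pooled list, 40.8% under the stricter p, 37.0% by summit and 48.1% in pooled peaks covered in both replicates, and 30.5% to 31.6% with a replicate left out. Of the gene lists, 11 reached the 95th percentile in promoter share, but 7 among pooled peaks covered in both replicates and 6 from the gene record's 5' end. With unmatched random lists, 9 instead of 6 were at or below the 5th percentile in promoter share, with pancreas, liver, tuft and immune genes gained and posterior Hox genes lost. With these, 9 lists instead of 3 were at or below the 5th percentile in width, with only 1 of the 3 among them, as the enteroendocrine and posterior Hox lists were lost, and 2 instead of 1 in distal peaks. Of the 10 widest domains, 5 stayed without joining and 4 with joining up to 3 kb. The CDX ratio turned to 0.717 over flanking windows. The number of words at a ratio of 1.2 was 13 also with 1 shuffled copy. For single lists, 170 promoter shares, 130 widths and 103 distal means stayed close to their value under an alternative, and 55, 70 and 97 moved. Close means a change smaller than the SD of the 2 replicate lists, or no change. Unmatched random lists are 1 of these alternatives and leave each list's own value unchanged, so they count as close by construction. Depth is unknown, so its limit on weak peaks could not be measured.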

Other observations

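Of the tests in this part, the rule of 1 shared base was chosen after its result was seen. The comparison with flanks of the same GC content was chosen after the ratio over all flanks was seen, but before its own values were. Chosen after its result was also the limit of 10 matching windows, below which a comparison of words near genes was left undecided.

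In each Hox cluster the median width was lower in the posterior groups than in groups 1 to 9, in both replicates. Whether this fall differed between clusters was not tested. In the Hoxa cluster all 3 genes of groups 10 to 13 had a promoter peak, with a median domain of 6188 bp against 14669 bp for its 8 genes of groups 1 to 9. That contrast was 6138 bp against 15031.5 bp in replicate 1 but 6182 bp against 8546 bp in replicate 2. In the Hoxc cluster 2 of 4 posterior genes were marked, and in the Hoxd cluster 3 of 4. With unmarked genes counted as 0 bp, the Hoxc median was 479 bp against 4069 bp for the 5 anterior genes (603 bp against 4239 bp in replicate 1, 619.5 bp against 2924 bp in replicate 2). The Hoxd median was 1309 bp against 3499 bp (1222 bp against 2616 bp in replicate 1, 796 bp against 3289 bp in replicate 2). Hoxb13, the only posterior gene of its cluster, had 1075 bp against 11168 bp (1166 bp against 7252 bp in replicate 1, 626 bp against 9448 bp in replicate 2). Among the genes of group 13, which pattern the hindgut's end, Hoxa13 and Hoxd13 had promoter signal values of 24.2 and 22.8, and Hoxb13 and Hoxc13 had 5.29 and 5.98. Of their neighbours, Hoxa10, Hoxa11, Hoxc10 and Hoxd10 had 6.44, 6.21, 3.68 and 4.70, and Hoxd11 had 14.0. These genes were chosen after their values were seen, and genes of a cluster share domains, so their widths are not independent.

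Chromosome X held 5.62 replicated peaks per Mb and chromosome Y 0.102, against 17.3 on the autosomes. Chromosome 11 was the densest, at 27.3 per Mb. These densities were not set against the number of genes, which differed too. Chromosome 11 held 1636 protein-coding genes in 118.7 Mb without gaps, chromosome X 948 in 163.5 Mb and chromosome Y 183 in 88.1 Mb.

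Replicate 2 had more peaks than replicate 1 (68124 against 57554), and they were narrower (median 358 bp against 516 bp). A fragment length set in peak calling is possible, as the shortest peaks measured 180 bp and 210 bp. Over 32928 replicated peaks covered in both replicates the median difference was 76 bases, more than 2 times those 30 bp. The bound set before the test counted this against the explanation. That bound takes each peak as 1 piece, and the number of pieces per region differed between the replicates, as given below. The test therefore cannot decide on the fragment length. A tail of weak short peaks was argued against as the whole cause, since the 30000 strongest peaks still had a median width ratio of 0.885, although part of the difference went with them (0.694 over the full lists). Regions broken into more pieces stayed open: 33333 shared domains held a mean of 1.65 peaks in replicate 2 and 1.46 in replicate 1, but covered bases also differed, at a ratio of 0.901. Depth and the differing controls could not be examined, and no biological explanation was tested.

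The replicated list held 9453 peaks that were not at least 50% covered in both replicates. A rule of 1 base shared with each replicate was argued against, because 89.5% of replicated peaks met it. A rule of 50% of either peak's length was argued against too, since 89.2% met it, although all 37825 pooled peaks that met it were in the list. The 4556 others were weaker (median signal value 3.68 against 9.44). Support from random subsets of the pooled reads stays open, as it cannot be examined without reads, and no biological explanation was tested.

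The CDX word was less frequent at distal summits than in flanking windows (ratio 0.717), although it was more frequent than in shuffled windows. Base composition is a possible explanation, as summits had a GC content of 51.6% and flanks 45.1%, and the word is rich in A and T. Against flanks of the same GC content the ratio was 1.26 (bootstrap 95% interval 1.22 to 1.31), which is consistent with composition as the source of the turn. The same comparison gave 2.19 for HNF4, 1.97 for FOXA, 1.56 for GATA, 1.89 for MEF2, 1.29 for TEAD, 1.02 for SRF and 0.923 for the NEUROD control. No biological explanation was tested.

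If CDX factors act mainly in the epithelium, their word should be more frequent at distal peaks near epithelial than near mesenchymal genes. It was present in 31 of 172 windows near 49 epithelial genes and in 8 of 68 near 27 mesenchymal genes, a difference at percentile 89.95 of swaps of genes between the lists, which leaves the hypothesis undecided. The HNF4 word was present in 3 and 1 of these windows (percentile 47.6) and the SRF word in 2 and 1 (percentile 32.2), too few to decide. The HNF4 value lay below the median of the swaps, which the bound set before the test counted against the hypothesis. It was left undecided because it rested on so few windows.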
